A study of Mus musculus with 6 samples.

How the data were processed

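Total RNA was extracted from the brains of 6 male mice after dissection, and biotinylated cRNA from 10 ug of total RNA was hybridised to one-colour Affymetrix arrays, per the labels. The genotype, age and replicate number of each animal were taken from the labels, which describe separate individuals and 1 genetic background for both groups. The submitters' processing notes name GCOS 1.4. Its settings and the algorithm behind the signal values are not given in the sources used here.

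The deposited values are linear signal intensities per probe set, never negative, with 12488 entries per array. The authors appear, from the values alone, to have scaled each array to 1 target, because the mean over the middle 96% of intensities was 300.2 on all 6 arrays. Such scaling would hide a change in total RNA content. No detection calls were used here. The ratio of 3' to 5' signal of the Gapdh controls was 0.826, 0.811 and 0.812 in knockout and 0.779, 0.798 and 0.768 in wild-type samples, with no overlap between the groups. That of actin was 1.22, 1.18 and 1.14 against 1.09, 1.08 and 1.20.

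The 66 control entries were set aside, leaving 12422 probe sets. In the platform annotation, which can be old, 10833 had 1 gene symbol, 396 several and 1193 none, and no gene was named from a probe set with several. Of the first kind, 10817 were found by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and served for gene order only. Values were transformed as log2(signal + 16), so folds of dim genes are understated. Probe sets with a mean log2 value at or above the 40th percentile (6.46, a signal of 72.2) were kept, 7453 in all. Suffixes such as _f_at, _s_at, _r_at, _g_at and _i_at mark probe sets that are less specific or hold fewer probes.

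Knockout and wild-type animals were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariates), and p values were adjusted by Benjamini and Hochberg's method over all kept probe sets with a threshold of 0.05. Differences are knockout minus wild type on the log2 scale. Ncam1 was also compared by an exact permutation test of 3 against 3. For gene lists, 1 probe set per gene was used, the one with the highest mean, which left 5665 genes. The 31 lists held 963 genes, of which 512 were measured, and were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. With an estimated correlation 0 of the 4 calls held. Genes near Ncam1 were counted at an adjusted p under 0.05, which gave 0, and at an unadjusted p under 0.01, and the second count was compared with that of all other genes by Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

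Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names every Ncam1 probe set and, in each direction, up to 12 genes that passed with no overlap between groups. Where fewer than 10 passed, it fills to 10 with the lowest p among probe sets with no overlap and a log2 difference over 0.5. It adds the 4 members with the lowest p in the direction of each called list, 2 of each other list described, the 5 neighbours of Ncam1 with the lowest p, and 12 genes fixed by name. Gabra6, Ppp1r17, Car8, En2, Gh, Cga, Canx, Pdia6, Dnajb9, Herpud1, Xbp1, Manf, Hsp90b1, St3gal4 and Tmem30a fall outside it and were named after their values were seen. So do Ada, Fos and Dusp1, which passed in fits that were not planned. Avp, Oxt, Hcrt, Gal and Chga, named in the closing sections, also fall outside the rule.

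The procedure was tested on simulated data, in 20 simulations of 7453 probe sets with 200 changed ones for the knockout against wild-type comparison. It recovered 38.2% of changes of 0.5 on the log2 scale, 89.7% of changes of 1 and 99.6% of changes of 2, with 5.05% false calls. These shares hold for 200 changed probe sets. With fewer changed, the adjustment demands a lower p and recovers less, which was not simulated. The real comparison called 2 probe sets, and Atp2c1 did not pass at a log2 difference of 1.04 (adjusted p = 0.153 in limma). A list shifted by 0.3 was called in 100% of simulations and unchanged lists in 0. The test of genes near Ncam1 gave a Fisher's exact p under 0.05 in 2 of 20 simulations without a shift and in 20 with one. The simulated genes were independent of each other.

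The alternatives were the replicate number as a block, age as a covariate, 2-month-old animals alone, each array left out, quantile normalisation, median centring, pseudocounts of 1 and 64, no filter and a stricter filter at the 60th percentile, no intensity trend, array weights, genes in place of probe sets, the mean of a gene's probe sets, and other windows around Ncam1. In comparing settings, a value that passed under neither setting was taken as having no direction.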

Results

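Gene expression was measured in total brain of 6 male C57BL/6J mice, 3 with a constitutive knockout of Ncam1, which encodes the neural cell adhesion molecule NCAM, and 3 wild-type animals. In each group replicates 1 and 2 were 2 months old and replicate 3 was 3 months old. Each brain was hybridised to its own one-colour Affymetrix array, so a group had n = 3 animals. Every array carried the same scaling, with a mean signal of 300.2 over the middle 96% of values and a median signal between 119.2 and 130.2. Log2 signals of the 7453 probe sets bright enough to be tested correlated between 0.967 and 0.985 for any pair of arrays. The number of arrays limits the precision, and the median standard error of a knockout minus wild-type difference was 0.12 on the log2 scale. The comparison asked which transcripts differ in the brain when NCAM is missing.

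The targeted gene was examined first. The brightest Ncam1 probe set had a signal of 270.8 ± 59.6 (SD, n = 3) in knockout brains and 1337 ± 116 in wild-type brains, a difference of -2.26 ± 0.15 (SE) on the log2 scale, or 4.78-fold lower. It was lower in all 3 knockout animals than in any wild-type animal, with an adjusted p of 0.00076 in limma. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 animals can give. A less specific Ncam1 probe set read 86.3 ± 14.9 against 147 ± 7.02 and did not pass (log2 difference -0.68 ± 0.15, adjusted p = 0.416 in limma). The remaining one was dim in both groups (5.75 ± 1.92 and 6.93 ± 2.10) and was not tested. Where the deleted part of the gene lies relative to these probe sets is not given in the sources used here, and a probe set outside the deleted part is no check of the deletion itself.

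**Figure D1:**
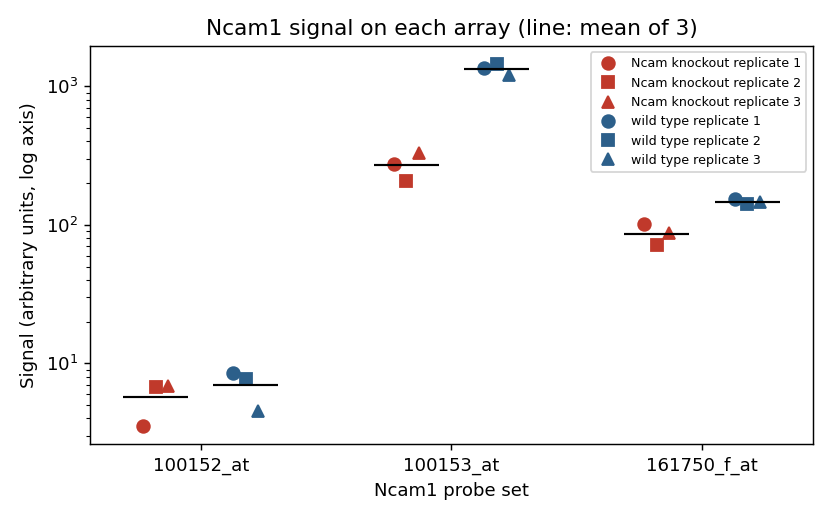
Signal of the 3 Ncam1 probe sets (horizontal axis) on each array, in arbitrary units on a log axis, with knockout arrays in red, wild-type arrays in blue, symbols for replicates 1 to 3 and a line at the mean of 3. For the brightest probe set the knockout arrays lie between 208.7 and 327.4 and the wild-type arrays between 1216 and 1448.

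Beyond Ncam1, 1 probe set passed the test across all genes. This probe set was higher in all 3 knockout brains than in any wild-type brain, with a signal of 335.6 ± 57.7 against 119.7 ± 17.5 and a log2 difference of 1.37 ± 0.15 (adjusted p = 0.0333 in limma). Its annotation joins 9 gene symbols, so no gene is named for it. Its call was lost when any 1 of the 6 arrays was left out (adjusted p 0.0697 to 0.148, and 0.0167 to 0.155 over all alternatives), while the log2 difference stayed between 1.24 and 1.44. In all, 1 probe set was higher and 1 lower after adjustment, and 243 were higher and 274 lower at an unadjusted p under 0.05. The signals of the 2 groups did not overlap for 960 probe sets, 12.9% of those tested, where chance gives 10%.

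Genes with the lowest p among those that did not pass, and with no overlap between the groups, are given next. Among higher values, Atp2c1, a calcium and manganese pump of the Golgi, read 912.3 ± 217 in knockout against 430.5 ± 58.5 in wild-type brains (log2 1.04 ± 0.17, adjusted p = 0.153 in limma). Rnf145 had a log2 difference of 0.65 ± 0.12, Nup107, a nuclear pore protein, 0.78 ± 0.15, and Rpl13a, a ribosomal protein, 0.56 ± 0.13. Among lower values, Mobp, a structural protein of myelin, read 1478 ± 148 against 2240 ± 181 (log2 -0.60 ± 0.09, adjusted p = 0.132), and its 3 other probe sets had log2 differences of -0.21, -0.22 and -0.42. Spg21 gave -1.65 ± 0.30, Pax4 -1.23 ± 0.20, H2-T18, a class I histocompatibility gene, -0.86 ± 0.14, and Acsf3, an acyl-CoA synthetase, -0.59 ± 0.12. The Spg21 and H2-T18 probe sets were of a less specific kind. Pax4 read 41.5 to 55.0 in knockout brains, below the filter limit of 72.2. Several further genes were separated by a single probe set that another probe set of the same gene did not match. Plekho1 had -1.16 and 0.11, Cd82, a tetraspanin, -0.62 and 0.11, Fnbp1 -1.36 and -0.08, Ccni 0.68 and -0.01, Dnajc8 0.83 and 0.02, Zfp91 0.53 and 0.01, and Camk2a 0.57 and -0.22. Znrf2 had 0.68, 0.29 and -0.20.

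Genes of oligodendrocytes and myelin were called lower as a group in knockout brains by camera at the preset correlation. Of 17 measured genes 13 had lower and 4 higher values, with a median log2 difference of -0.21 (camera, adjusted p = 3.48e-05). The list did not pass with camera at an estimated correlation between genes (adjusted p = 0.264 with an estimated correlation) or with fry (adjusted p = 0.105). Cryab, a small heat shock protein measured by a less specific probe set, read 218.1 ± 8.13 against 305.2 ± 25.6 (log2 -0.45 ± 0.10). Mag, the myelin-associated glycoprotein, read 759.2 ± 112 against 1030 ± 108 (-0.44 ± 0.12), Ugt8a, which makes the myelin lipid galactosylceramide, 233.8 ± 16.5 against 321.2 ± 35.8 (-0.43 ± 0.11), and Qdpr, a pteridine reductase, 3509 ± 204 against 4127 ± 158 (-0.23 ± 0.06). A second, dim Mag probe set had 0.25 ± 0.19. No member passed among all probe sets, and 5 were lower when adjusted over the list alone, namely these 4 and Mobp. The list medians of knockout replicates 1, 2 and 3 were -0.08, -0.15 and -0.19 against the wild-type mean, and those of the wild-type animals 0.01, 0.06 and -0.06. Without knockout replicate 3 the median was -0.14 (adjusted p = 0.00184) and without wild-type replicate 2 it was -0.11 (adjusted p = 0.00306).

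Genes of the heat shock and unfolded protein response were called higher as a group in knockout brains, although not in every animal. Of 24 measured genes 19 had higher values, with a median log2 difference of 0.10 (camera, adjusted p = 0.00166). The list did not pass with camera at an estimated correlation (adjusted p = 0.603 with an estimated correlation), with fry (adjusted p = 0.583) or with array weights (median 0.05, adjusted p = 0.0947). The list medians of knockout replicates 1, 2 and 3 were -0.01, 0.11 and 0.20, and those of wild-type replicates 1, 2 and 3 were -0.04, 0.00 and 0.07, so the groups overlapped. Hspa5, a chaperone of the endoplasmic reticulum, read 2809 ± 490 against 1972 ± 99.8 (log2 0.49 ± 0.11), the disulfide isomerases Pdia4 and Pdia3 had log2 differences of 0.57 ± 0.15 and 0.54 ± 0.18, and Creld2, which responds to stress of that compartment, had 0.47 ± 0.17. Further genes of the endoplasmic reticulum, chosen after their values were seen, went both ways or stayed near 0. Xbp1 had 0.30 ± 0.13, Manf 0.13 ± 0.17, Hsp90b1 0.09 ± 0.07, Herpud1 0.05 ± 0.12, Dnajb9 0.01 ± 0.14, Pdia6 -0.01 ± 0.10 and the chaperone Canx, whose p was lower than that of Creld2, -0.30 ± 0.11. Over all probe sets 0 members passed, and 1, Hspa5, was higher when adjusted over the list alone. The Gapdh control, whose 3' to 5' ratio is a sign of RNA quality, had ratios of 0.811 to 0.826 in knockout and 0.768 to 0.798 in wild-type samples without overlap, so neither this list nor the myelin list was compared free of that difference. Without knockout replicate 3 the list median was 0.02 (adjusted p = 0.294), without knockout replicate 1 it was 0.19 (adjusted p = 5.68e-07) and without wild-type replicate 2 it was 0.06 (adjusted p = 0.00661).

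Cerebellar genes were lower in knockout brains as a group, and for most of them the difference came from 1 animal. All 14 measured genes had lower means, with a median log2 difference of -0.59 (camera, adjusted p = 3.48e-05). The list did not pass with camera at an estimated correlation (adjusted p = 0.603 with an estimated correlation) or with fry (adjusted p = 0.583). Gabra6, the GABA receptor subunit of cerebellar granule cells, read, by its brighter probe set, 11.8 in knockout replicate 2 and between 1254 and 1388 on the other 5 arrays. Ppp1r17, a Purkinje cell gene, read 15.1 there by its brighter probe set and between 358.5 and 437.3 elsewhere. In the same animal Car8 read 105.7, En2 103.9 and Cbln1 246.1, where the lowest of the other arrays gave 1066, 589.3 and 873.3. Zic1 read 1693 ± 770 against 2325 ± 67.2 and Pcp2 413.2 ± 173 against 584.4 ± 43.4. Kcnc1, a potassium channel and the member with the lowest p, was an exception, with 54.3, 71.1 and 69.4 in knockout replicates 1, 2 and 3 against 97.5 to 113.4 in wild-type animals. None of the 14 genes passed, over all probe sets or adjusted over the list alone. The list median was -1.43 in knockout replicate 2, -0.13 and 0.02 in knockout replicates 1 and 3, and between -0.06 and 0.07 in wild-type animals. Without knockout replicate 2 the median was -0.05 (adjusted p = 0.359).

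Pituitary genes were higher in knockout brains as a group, again with 1 animal far from the rest. Of 8 measured genes 7 had higher means, with a median log2 difference of 0.58 (camera, adjusted p = 0.00852). This call was lost with camera at an estimated correlation (adjusted p = 0.603 with an estimated correlation) and with fry (adjusted p = 0.583). Gh, growth hormone, read 11610 in knockout replicate 1 and between 222.4 and 409.7 on the other arrays. Prl, prolactin, read 2141 against 43.9 to 161.2, Pomc, the corticotropin precursor, 704.1 against 34.4 to 171.8, and Cga, the common subunit of the glycoprotein hormones, 524 against 60.9 to 97.7. Ghrhr and Lhb had log2 differences of 0.30 ± 0.15 and 0.22 ± 0.11. Knockout replicates 2 and 3 also lay above every wild-type animal for Prl (131.3 and 161.2 against at most 108.7) and Pomc (171.8 and 132.7 against at most 127.5). The same held narrowly for Lhb (392.8 and 380.4 against at most 379.2), whereas the groups overlapped for Ghrhr. No member passed over all probe sets or adjusted over the list alone. Without knockout replicate 2 the median was 0.94 (adjusted p = 0.00102). The list did not pass without knockout replicate 1 (median 0.18, adjusted p = 0.0624) or without the filter on dim probe sets (0.26, adjusted p = 0.052).

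**Figure D2:**
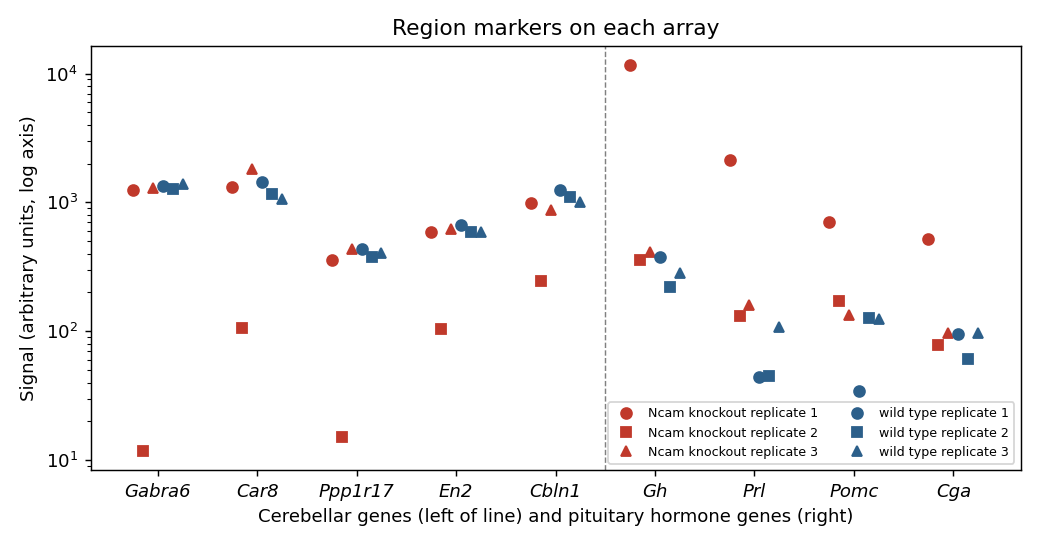
Signal of 5 cerebellar genes (left of the dashed line) and 4 pituitary hormone genes (right) on each array, in arbitrary units on a log axis, with knockout arrays in red, wild-type arrays in blue and symbols for replicates 1 to 3. Knockout replicate 2 is lowest for each cerebellar gene, down to 11.8 for Gabra6, and knockout replicate 1 is highest for each hormone gene, up to 11610 for Gh.

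Knockout replicate 3, whose cerebellar list median lay within the wild-type range and whose pituitary list median, at 0.40, was far below that of knockout replicate 1 but above every wild-type animal, was also set alone against the wild-type animals. In this comparison, added after the data had been seen, Ncam1 was the 1 probe set called. The animal was already part of the main comparison and had the most extreme list medians of the 3 knockout animals for myelin (-0.19) and for the heat shock and unfolded protein response (0.20), so its values add no independent evidence on either list. It was 3 months old and 2 of the 3 wild-type animals were 2 months old, and the 3-month-old wild-type animal lay at 0.07 for the heat shock list. The single knockout animal is assumed to vary like the wild-type animals.

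Genes tied to NCAM by its known biochemistry did not pass as groups. Of 21 measured signalling partners 14 had lower and 7 higher values (median log2 difference -0.04, camera adjusted p = 0.436), with 0 called over all probe sets and 0 adjusted over the list alone. Fgfr1, the fibroblast growth factor receptor that NCAM binds, had -0.23 ± 0.11, Map2k2 -0.20 ± 0.10, the kinase Fyn -0.23 ± 0.13, Prnp, the prion protein, 0.02 ± 0.05, Gap43 -0.02 ± 0.12 and Bdnf 0.17 ± 0.11. The test fry, which asks whether the members of a list move 1 way on balance without setting them against other genes, placed this list lower (adjusted p = 0.0191). Enzymes of sialic acid, polysialic acid and HNK-1 glycan synthesis had a median of -0.01 over 17 genes (adjusted p = 0.986), with 0 called over all probe sets and 0 adjusted over the list alone. The polysialyltransferases St8sia2 and St8sia4, which modify NCAM, had -0.16 ± 0.11 and 0.16 ± 0.16, and the ganglioside synthesis genes B4galnt1 and St3gal5 0.33 ± 0.09 and 0.30 ± 0.09. At an unadjusted p under 0.05 in limma 2 genes of this list were higher and 1 was lower, the sialyltransferase St3gal4 at -0.67. Other adhesion molecules of the immunoglobulin and cadherin families had a median of 0.06 over 17 genes (adjusted p = 0.660), with 0 called in either way. Ncam2, the closest relative of Ncam1, read 95.7 ± 21.6 against 107.6 ± 34.9 (-0.13 ± 0.23), L1cam had 0.15 ± 0.14, Chl1 0.09 ± 0.11, Cdh4 0.45 ± 0.23 and Icam5 0.15 ± 0.10.

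Neuronal, glial and regional lists gave few differences apart from those above. Voltage-gated ion channels had 12 of 19 genes lower (median log2 difference -0.06), led by Kcnc1 at -0.59 ± 0.17 and the T-type calcium channel Cacna1g at -0.44 ± 0.12. The list did not pass with camera (adjusted p = 0.126, and 0.603 with an estimated correlation), and was lower with fry (adjusted p = 0.00527) and with camera on the mean of each gene's probe sets (median -0.10, adjusted p = 0.0237), with 0 members called over all probe sets and 0 adjusted over the list alone. Vascular cells and meninges (median -0.09, adjusted p = 0.0525), astrocytes (-0.06, adjusted p = 0.0525) and striatum (0.16, adjusted p = 0.0529) lay closest to the threshold. Of the vascular list 1 gene was higher and 1 lower when adjusted over the list alone, and none of the astrocyte or striatal genes was called. Anxa2 had 0.44 ± 0.11, Igfbp2 -0.34 ± 0.08, S100b, an astrocyte calcium-binding protein, -0.41 ± 0.14, and Ndrg2 -0.17 ± 0.06 by its brighter probe set and 0.09 ± 0.08 by the other. The striatal list was highest in knockout replicate 2, at 0.40, the animal with low cerebellar signal, and without it the median was 0.04 (adjusted p = 0.459). The striatal list passed under 6 of 21 alternatives and the vascular and astrocyte lists under 4 each, and none of them passed with an estimated correlation (adjusted p = 0.603 with an estimated correlation for striatum and 0.496 for the others). Presynaptic vesicle genes had a median of -0.01 (adjusted p = 0.289), with 1 lower when adjusted over the list alone, Sypl at -0.43 ± 0.09. Dcx and Th, markers of migrating neuroblasts and of catecholamine neurons, had 0.06 ± 0.12 and -0.05 ± 0.16. The remaining lists had adjusted p values from 0.289 to 0.986. The median, the mean and the test differed in sign for axon growth, glutamatergic synapse, pan-neuronal, monoamine, hippocampal and glucocorticoid genes.

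**Figure D3:**
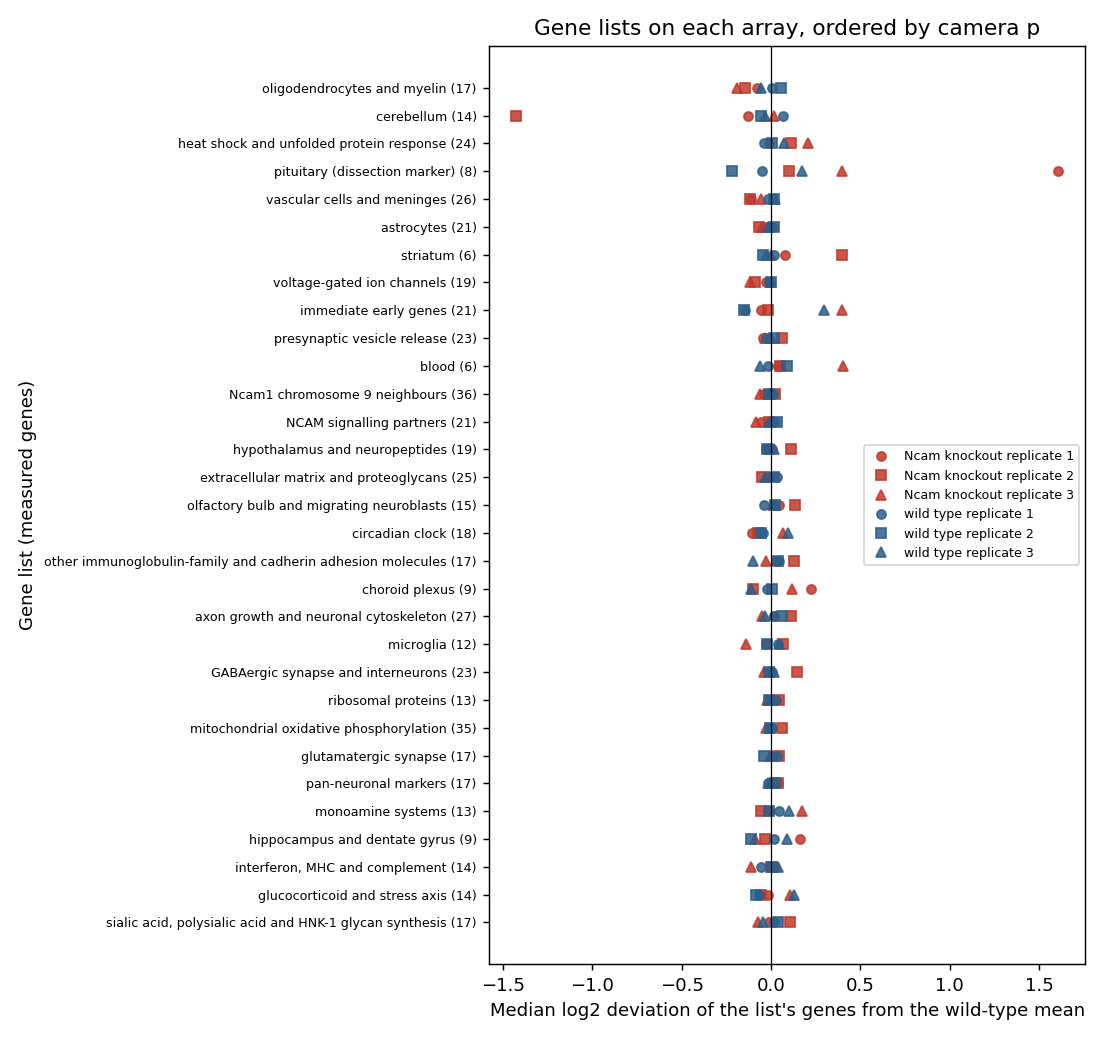
Median log2 deviation of each gene list from the wild-type mean (horizontal axis) on each array, with 31 lists ordered by camera p and the number of measured genes in brackets, knockout arrays in red and wild-type arrays in blue. The cerebellum list lies at -1.43 in knockout replicate 2 and the pituitary list at 1.61 in knockout replicate 1.

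Genes close to Ncam1 on chromosome 9 were more often at low unadjusted p than genes elsewhere. At the first threshold planned, an adjusted p under 0.05 in limma, 0 of 71 genes within 10 Mb of Ncam1 passed, and 13 had an unadjusted p under 0.05. At the second threshold planned, 4 of 71 tested genes (5.63%) had an unadjusted p under 0.01 in limma, against 85 of 5593 other genes (1.52%), an odds ratio of 3.87 with a 95% interval of 1.00 to 10.7 (two-sided Fisher's exact test, p = 0.0249). The 4 genes were Fxyd2, a regulatory subunit of the sodium pump (138.3 ± 38.9 in knockout against 45.9 ± 21.2 in wild-type brains, log2 1.35 ± 0.30), Pts, an enzyme of tetrahydrobiopterin synthesis (97.9 ± 25.0 against 177.9 ± 19.5, -0.79 ± 0.18), Cryab, which also stands in the myelin list, and Pafah1b2, a subunit of a platelet-activating factor hydrolase (1233 ± 71.8 against 1530 ± 78.9, -0.31 ± 0.07). Phldb1 followed at -0.27 ± 0.09. Fxyd2 read 65.2, 23.2 and 49.4 in wild-type replicates 1, 2 and 3, all below the filter limit of 72.2. The Cryab probe set was of a less specific kind. The other Pafah1b2 probe sets had -0.09 ± 0.09 and -0.38 ± 0.10. In the list of neighbours fixed beforehand, 1 gene was higher and 3 lower when adjusted over the list alone, out of 36, and the list did not shift as a whole (median -0.05, camera adjusted p = 0.387). All 4 genes past unadjusted p 0.01 lay within 5 Mb, where they made up 4 of 27 genes (odds ratio 11.3, interval 2.79 to 34.2, Fisher's exact p = 0.000758). Within 20 Mb there were 7 of 117 (odds ratio 4.24, interval 1.62 to 9.42, Fisher's exact p = 0.00228). That window contains the same 4 genes, and none of its others lay between 5 and 10 Mb. The part beyond 5 Mb was not tested alone, so the wider window does not show where the excess ends. Outside 10 Mb on chromosome 9, St3gal4, Spg21, Anxa2, Tmem30a and Atp2c1 also had an unadjusted p under 0.01 in limma. In the 2-month-old animals alone the 5 Mb odds ratio was 6.01 and did not pass (exact p = 0.0502). The 10 Mb result did not pass without knockout replicate 2 (2.72, Fisher's exact p = 0.0693), without wild-type replicate 1 (3.83, p = 0.105 in the same exact test), in the 2-month-old animals alone (3.33, exact p = 0.0694) or with a stricter filter on dim probe sets (2.28, exact p = 0.231), and without knockout replicate 1 it rose to 8.62 (exact p = 4.31e-05).

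**Figure D4:**
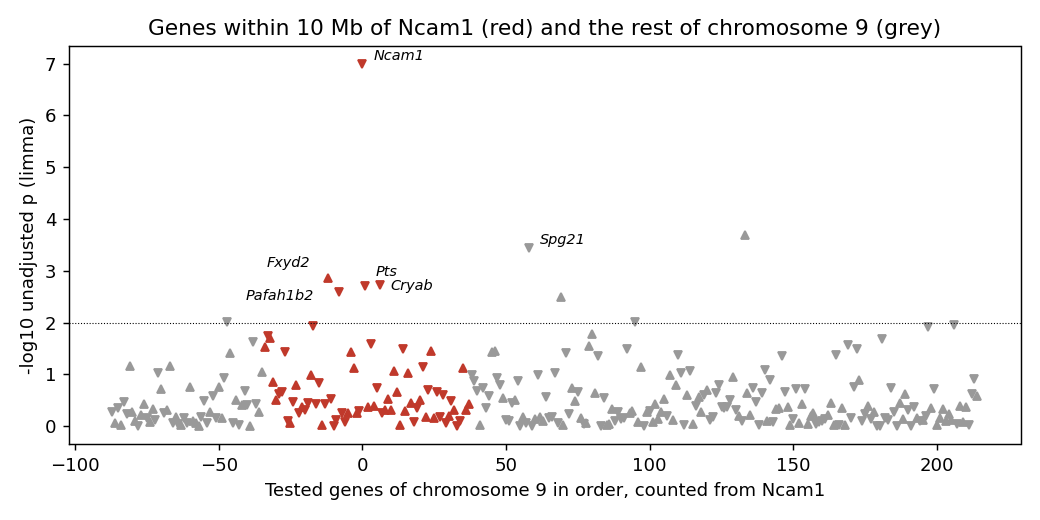
Unadjusted limma p of each tested gene on chromosome 9, as -log10 p (vertical axis), against the order of the genes counted from Ncam1 (horizontal axis), with genes within 10 Mb in red and the others in grey, upward triangles for higher and downward for lower values in knockout, and a dotted line at p of 0.01. Apart from Ncam1, 4 red genes lie above the line.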

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

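The tests of the cerebellar and pituitary patterns and of both windows without knockout replicates 1 and 2 together were chosen only after these results had been seen. For the 10 Mb window, the fits with each array left out were planned. Their use to weigh tissue differences was chosen afterwards. The term for genotype by age was not among the planned tests.

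Cerebellar genes were far lower in knockout replicate 2 than on any other array. The knockout genotype as the whole cause is argued against by knockout replicates 1 and 3, whose list medians averaged -0.056 on the log2 scale beside -1.43 in replicate 2. Degraded RNA is argued against by the Gapdh 3' to 5' ratio of that array, 0.811, within the range of the other 5 arrays. A brain sample from which cerebellar tissue was missing remains as a candidate explanation, and no record of the dissection was available to test it. On that array 13 of the 14 list genes had their lowest value. This count restates the pattern and cannot tell missing tissue from another cause of low cerebellar signal. Without this array the list median was -0.0495.

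Pituitary hormone genes were far higher in knockout replicate 1. The knockout genotype as the whole cause is argued against by knockout replicates 2 and 3, whose list medians averaged 0.25 beside 1.61, and more hypothalamus in the sample by the median of Avp, Oxt, Hcrt and Gal, -0.0924. Pituitary tissue included in that sample remains as a candidate explanation. There 4 of 4 hormone genes, products of different pituitary cell types, were at least 2-fold above the next array. The excess was 27.3-fold for Gh, 12.2 for Prl, 4.75 for Cga and 3.84 for Pomc. These 4 were set for the test after their values were seen, so the count restates the pattern and does not test the explanation. Of the 8 list genes, Pomc and Chga also stand in the hypothalamic list. A smaller effect of genotype on these genes was not excluded.

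Genes near Ncam1 were more often at an unadjusted p under 0.01 than other genes. The tissue differences of knockout replicates 1 and 2 as the cause are argued against for the 5 Mb window. Its odds ratio was 22.3 without the first and 7.99 without the second (interval 1.98 to 23.9). They stay open for the 10 Mb window, with 2.72 without the second (0.709 to 7.48). Without both, knockout replicate 3 alone remained against the wild-type animals, and the odds ratios were 6.44 for 5 Mb and 2.81 for 10 Mb. The intervals treat genes as independent and do not measure the spread between animals. A donor-strain segment kept around the targeted gene may account for the pattern, although the labels give both groups 1 genetic background. Of 5020 overlapping windows of 27 consecutive tested genes elsewhere, 0% held as many genes past p of 0.01 (highest count 3, against 4). This scan took its size from the 5 Mb window and was not run for the 10 Mb window. It shows that such genes cluster near Ncam1 and does not single out a donor-strain segment. An effect of the targeted allele on its neighbours predicts the same and was not tested. With 10 splits of the 6 arrays no share under 0.05 can be reached, and the real split gave 3.87 for the 10 Mb window, the highest other 2.09, so that 1 split, the real one, was as high.

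The same limit of 10 splits holds for the counts of calls. The real split gave 2 probe sets past adjustment, reached by 1 split, the real one, and the highest other gave 1. Of the 2, 1 was Ncam1, the targeted gene, whose difference is set by the design. Apart from it the real split gave 1, no more than the highest other. It gave 4 gene lists, a number reached by 4 splits with the real one included, and the highest other gave 7, in the split that sets knockout replicates 1 and 3 and wild-type replicate 3 against the rest.

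A control probe set outside the comparisons, for the 3' part of 18S ribosomal RNA, was higher in every knockout animal than in any wild-type animal, by 0.272 on the log2 scale (336.5, 344.8 and 374.8 against 280.8, 268.2 and 318.9). It was picked for its lack of overlap, and the groups overlapped for all other mouse control probe sets examined. Chance gives no overlap for 10% of probe sets, so its separation is no evidence of a difference. The 3-month group holds 1 animal per genotype, so that a difference between single animals cannot be told from one that depends on age. Limma's term for genotype by age passed for 2 probe sets, with 425 at an unadjusted p under 0.05, and these are given as values only. For Ada, adenosine deaminase, the difference was 3.642 log2 units more positive at 3 months (70.8, 82.4 and 421.7 in knockout, 310.8, 248.9 and 95.6 in wild-type replicates 1, 2 and 3, adjusted p = 0.0294). For a probe set annotated with 3 gene symbols it was 2.823 units more positive (289, 326.3 and 418.9 against 342.5, 393.1 and 56.8, adjusted p = 0.0294).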

How the results depend on the processing

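The comparison of knockout replicate 3 alone with wild type was added after the data had been seen. The Ncam1 difference passed under all 18 alternatives, from -1.97 to -2.46 on the log2 scale. Probe sets higher numbered 0 with quantile normalisation, median centring, no filter, no intensity trend, genes in place of probe sets and knockout replicate 3 alone, and 0 to 1 when arrays were left out. Probe sets lower numbered 2 in 2-month-old animals (Ncam1 and Spg21), 3 with array weights (Ncam1, Spg21 and Plekho1), and 1 to 2 when arrays were left out. The 1 probe set called higher was Atp2c1 without knockout replicate 2, and in 2-month-old animals and without wild-type replicate 3 it was a probe set with 2 gene symbols that read 919.2, 976.4 and 1348 in knockout and 299.7, 286.9 and 1255 in wild-type replicates 1, 2 and 3, in place of the one with 9.

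Lists called numbered 0 with an estimated correlation, 2 with fry and 3 to 7 when arrays were left out, 7 without knockout replicate 1. With camera at an estimated correlation and with fry the medians stay as they were, -0.585 for cerebellum, 0.579 for pituitary, -0.215 for myelin and 0.0954 for the heat shock and unfolded protein response, so the tests alone differed. The estimated correlations were 0.729, 0.441, 0.0117 and 0.243 in that order, beside the preset 0.01. With an estimated correlation camera also takes its degrees of freedom from the arrays and not from the genes, and for myelin, whose estimate lay near the preset, this ended the call. The myelin list passed in each fit with 1 array left out, from -0.113 to -0.212. The heat shock list had 0.0531 with array weights and 0.0203 to 0.193 when arrays were left out. Cerebellum ranged from -0.757 to -0.0495 when arrays were left out and was 0.0164 in knockout replicate 3 alone. For that animal camera at the preset correlation called 4 lists, myelin and presynaptic vesicle release lower and heat shock and immediate early genes higher, with no test at an estimated correlation. Pituitary had 0.263 without the filter, 0.399 in knockout replicate 3 alone and 0.185 to 0.94 when arrays were left out, and the stricter filter left too few pituitary genes to test. The odds ratio of Ncam1 neighbours was 3.33 in 2-month-old animals, 2.28 with the stricter filter and 2.72 to 8.62 when arrays were left out. For the settings other than arrays left out and the set tests, the cause was not tested.

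With the replicate number as a block, 2 probe sets, the same 2, and 6 lists were called, the 4 and, higher, striatum and immediate early genes. Nothing in the labels says that the numbers pair the animals, and deviations from the group means correlated by 0.015, 0.147 and 0.201 for equal numbers, with knockout replicate 1 closest to wild-type replicate 2 (0.081). Striatum was also called higher in 2-month-old animals, without knockout replicate 1, knockout replicate 3 or wild-type replicate 1, and with quantile normalisation. Vascular genes were called lower without knockout replicate 1 or wild-type replicate 1, with quantile normalisation and without the filter, and astrocyte genes in 2-month-old animals, without knockout replicate 1 or wild-type replicate 3 and with median centring. Immediate early genes were called under 4 alternatives, voltage-gated channels under 2, and blood, presynaptic vesicle release and NCAM signalling partners under 1 each. With age as a covariate 2 probe sets and 4 lists were called. Probe sets whose mean log2 value over the 6 arrays lay below 6.46 were not tested.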

Other observations

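The fit for age was chosen after the data had been seen. Immediate early genes, which respond within minutes to neuronal activity and handling, were higher in both 3-month-old animals than in the 4 animals of 2 months. Their median difference was 0.40 on the log2 scale over 21 genes (camera, adjusted p = 2.09e-10, adjusted p = 0.15 with an estimated correlation). Fos read 809 and 668.1 in the 3-month-old knockout and wild-type animals and between 113.9 and 304.4 in the others (log2 1.93 ± 0.19 SE, adjusted p = 0.0363 in limma). Dusp1, a phosphatase of the same response, read 1178 and 1138 against 513.4 to 607.2 (1.08 ± 0.08, adjusted p = 0.0113). These were the 2 probe sets past adjustment for age, with 924 at an unadjusted p under 0.05. Age cannot be separated here from anything else that those 2 animals shared.

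Other lists also differed with age in camera and not with an estimated correlation. Glucocorticoid and stress genes (0.18, adjusted p = 0.00661, 0.592 as the p with an estimated correlation) and heat shock and unfolded protein response genes (0.17, adjusted p = 0.00661, 0.85 in the same order) were higher at 3 months, and axon growth genes were lower (-0.12, adjusted p = 0.00661, 0.781 likewise). The cerebellum list was higher (0.38, adjusted p = 0.0195, 0.85 likewise), where the 2-month group holds knockout replicate 2.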
